A study of Homo sapiens with 24 samples.

How the data were processed

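MicroRNAs (miRNAs), short non-coding RNAs that repress messenger RNAs, were measured on 24 single-colour arrays. Per the labels, the material was Panc1, an established human pancreatic cancer cell line, either in culture or grown as a subcutaneous tumour in mice. The labels' protocols state that total RNA was labelled with Hy5 and hybridised to a custom miRNA array. There were 9 control and 9 metformin arrays of cultured cells, and 3 control and 3 metformin arrays of tumours. Metformin, a biguanide used against type 2 diabetes, was given to cells at 10 mM for 72 h. Tumour-bearing mice received 1 or 2 mg per body by intraperitoneal injection, 5 times a week for 5 weeks. The labels do not say which tumour had which dose, so the treated tumours were 1 group.

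The values used are the authors' processed intensities, deposited as 1 table of 1212 rows and 24 columns. They are linear and positive, on an arbitrary scale, and 640 cells are blank. The scanner, background correction, rule for blanks and normalization are not given in the sources used here. Each column's median lies between 22.7 and 24.6, so the arrays lie close to a common level as deposited. Below an intensity of 60, between 98.5% and 100% of the distinct values of an array lie on an evenly spaced grid with 1 offset, to within 0.1 of its spacing. This grid was set against the values only after they were seen. Applying 1 factor and 1 constant to an array keeps such a grid, and quantile or other curved scaling does not. How the factor and constant were chosen is not given in the sources used here. Blanks fell mostly on dim probes: the median blank was at a probe in the 13.4th percentile of median intensity. No row has more than 7 blanks, and 879 rows have values on all 24 arrays.

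Rows are identified by accession numbers of mature miRNAs, 1206 by a single number and 6 by several joined numbers. The series' design text speaks of 1042 human probes, and the rows do not mark which these are, so all 1212 were kept. Neither the table nor the reference gene table used here pairs these numbers with miRNA names (0 were found in it). Probes are therefore given by number, at most 2 that rose and 2 that fell in a comparison. The rule fixed before the data were examined took up to 10 probes in each direction, by the largest log2 change past the threshold, and gave probes without a name only as counts. The numbers printed here depart from it: they keep its order, and the limit of 2 was chosen after the data were seen. The families, clusters and cell type markers listed beforehand could not be tested. Genome positions are likewise not given.

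Intensities were taken to log2 without a pseudocount, and blanks were treated as missing. Group differences were tested with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. A log2 change is the difference of group means of log2 intensity, with its standard error (SE) from the moderated variance. Cells and tumours were each fitted on their own arrays, and untreated tumours were set against untreated cells on the control arrays. The difference between the metformin effects was an interaction contrast over all 24 arrays. In cells a probe needed values on at least 6 arrays of one group and 2 of the other. In tumours it needed values on at least 2 arrays of each group. Between untreated materials it needed at least 6 control cell arrays and 2 control tumour arrays, and for the interaction at least 2 arrays of each of the 4 groups and 6 of a cell group. These rules removed no probe in cells. Levels in the text are means of the deposited intensities with their standard deviation (SD). Probes were also divided by mean level (the mean over the arrays of a comparison, on the log2 scale) at 50, 100 and 500 units, limits chosen after seeing the data.

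On data simulated from each comparison's own residual spread, with 200 changed probes in each of 10 runs, 84.5% of 1.5-fold changes were recovered among the 1212 probes of the cell comparison and 99.7% of 2-fold changes. Among the 1182 probes of the tumour comparison the shares were 54.3% and 84.0%. For the interaction on 1182 probes they were 22.5% and 69.0%, and for untreated tumours against cells on 1202 probes 46.6% and 91.2%. False calls made up between 4.13% and 5.58% of all calls, and a run without changes gave 0 calls in each comparison. The simulated noise was independent between arrays and between probes, so these shares do not cover deviations that real arrays or probes have in common. The real data gave fewer calls than 200 in cells (23), in tumours (78) and for the interaction (13). The Benjamini-Hochberg adjustment is stricter when fewer probes change, so for changes that sparse the recovered shares may be too high.

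No 2 arrays held identical values. Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure the spread between these arrays, which may be partly technical. No slide or scan date was used.

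Alternatives fixed beforehand were quantile normalization, centring on the median or the 75th percentile, 16 units added before log2, other filters, a level-dependent prior variance, array weights, a 1.5-fold minimum, the replicate number as a block, all arrays in 1 fit, an unmoderated test and leaving out each array. Centring on the 25th percentile and a mean level of at least 100 were added after seeing the data. Tests of miRNA lists were not run. Counts of calls were also set against other splits of the arrays. Precision is limited by the number of arrays, and intensity over background could not be computed.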

Results

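The expression of miRNAs was measured in Panc1 pancreatic cancer cells in culture and in Panc1 tumours grown under the skin of mice, each with and without metformin. The question named by the series is which miRNAs accompany the drug's effect on this cancer. Most probes were dim. In control cells 97.9 ± 11.2 probes (SD, n = 9) reached 100 units, against an array median of 24.1 ± 0.351 (SD, n = 9), and in metformin-treated cells 99.6 ± 9.18 (SD, n = 9). Untreated tumours held about 2.09 times as many such probes, 204 ± 8.39 (SD, n = 3), and metformin tumours 187 ± 6.66 (SD, n = 3). The 10 brightest probes carried 53.1% ± 2.64 of the summed intensity in control cells (SD, n = 9) and 38.1% ± 0.0962 in control tumours (SD, n = 3). Replicate arrays correlated across probes (log2 values, Pearson's r) with medians of 0.945 in control cells, 0.954 in metformin cells, 0.982 in control tumours and 0.984 in metformin tumours, whereas cell and tumour arrays correlated with a median of 0.865. Such correlations describe similarity only, since probes are not independent replicates.

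**Figure D1:**
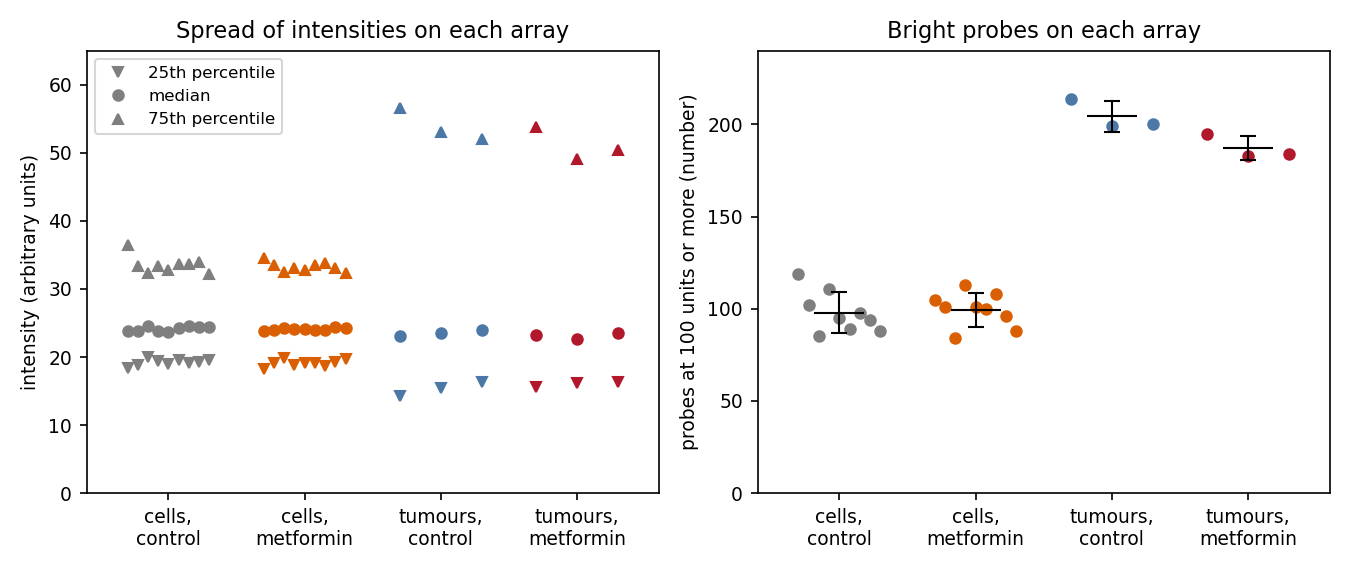
Intensity of each of the 24 arrays in arbitrary units (left; 25th percentile, median and 75th percentile of the probes) and number of probes at 100 units or more (right; bars give mean and SD), by group. Array medians lie between 22.7 and 24.6, while the 75th percentile averages 33.5 in control cells and 53.8 in control tumours.

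Cultured cells were compared with and without metformin. Of 1212 probes, 23 passed the threshold, 12 higher and 11 lower with metformin, and the median change among them was 1.52-fold up and 1.53-fold down. The control and treated arrays did not overlap for 1 of the 23, the only such probe among all 1212 (0.0825%), where chance gives 0.00411% of probes. MIMAT0000252 was the only called probe that changed at least 2-fold, with overlapping arrays: it fell from 67.8 ± 20.1 in control cells (SD, n = 9) to 32.8 ± 8.89 with metformin (SD, n = 9), a log2 change of -1.04 (SE 0.16, limma adjusted p = 4.65e-05). MIMAT0000453 fell from 34.4 ± 11.6 to 20.1 ± 3.77 (SD, n = 9 each; log2 change -0.71, SE 0.17, limma adjusted p = 0.0101). MIMAT0002872 rose from 17.0 ± 4.69 to 26.9 ± 5.50 (SD, n = 9 each; log2 change 0.69, SE 0.15, limma adjusted p = 0.00738), from below the mean 25th percentile of the control arrays (19.2). MIMAT0001341, well above the array median, rose from 228 ± 56.6 to 361 ± 59.4 (SD, n = 9 each; log2 change 0.68, SE 0.15, limma adjusted p = 0.00667). The call of MIMAT0000453 ended after quantile normalization and with the unmoderated test, its adjusted p ranging over the alternatives from 0.000329 to 0.129. That of MIMAT0002872 ended with the unmoderated test only.

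By level, the directions in cells were as follows, without a test between levels. Of the 1040 probes with a mean level under 50, 6 rose and 10 fell. Among the 134 probes from 50 to under 500, 3 rose and 1 fell, and all 3 changed probes among the 38 at 500 or more rose. The 5 changed probes with a mean level of at least 100 all rose, against a median log2 change of 0.11 over the 100 probes of that level. Whether the summed deposited intensity moved was tested separately, over probes with values on all arrays. The sum was 1.04 times higher with metformin, a difference within the spread of the arrays (exact two-sided permutation p = 0.535, adjusted 0.701 over 9 such array-level tests). The arrays were deposited near a common level, so this sum cannot show whether the total miRNA signal changed. Without any fold minimum, 182 probes had an unadjusted p under 0.05 where 60.6 were expected by chance. The count of 23 was 12 without control replicate 8, 14 without metformin replicate 1 and 13 with an unmoderated test per probe. With a minimum of 1.5-fold it was 14. Some alternatives raised it: 32 without control replicate 1, 33 with array weights, and more still with the replicate number as a block, as given below.

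**Figure D2:**
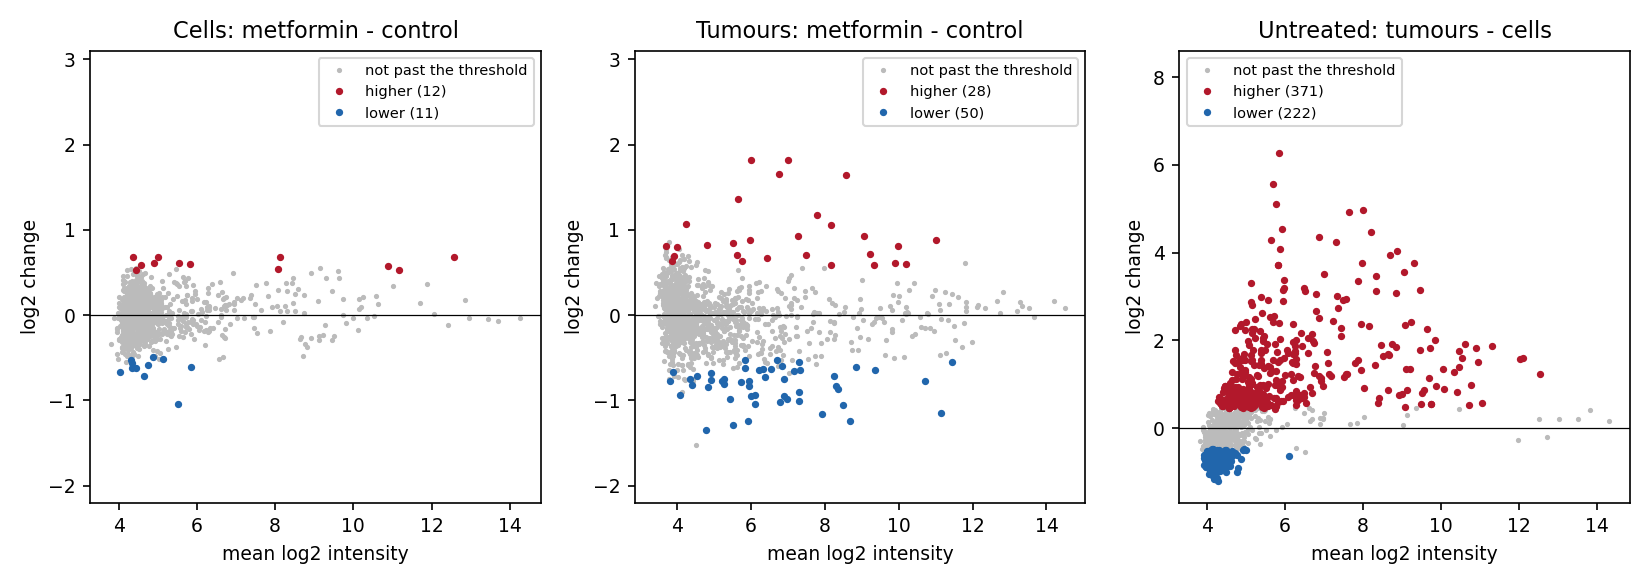
Log2 change against mean log2 intensity for each probe in cells (left), tumours (middle) and untreated tumours against untreated cells (right), on axes of different range. Red and blue points are probes past an adjusted p of 0.05: 12 and 11 in cells, 28 and 50 in tumours, and in the right panel 371 are higher in tumours.

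Tumours of treated and untreated mice were compared in the same way. Of 1182 probes, 78 passed the threshold, 28 higher and 50 lower in metformin-treated tumours, with median changes of 1.76-fold up and 1.71-fold down, and 18 changed at least 2-fold (8 up, 10 down). MIMAT0000433 rose the most among them, from 67.9 ± 8.09 in control tumours (SD, n = 3) to 240 ± 19.6 with metformin (SD, n = 3), 3.54-fold (log2 change 1.82, SE 0.15, limma adjusted p = 0.00156). MIMAT0000451 rose from 34.0 ± 1.65 to 122 ± 22.2 (SD, n = 3 each), also 3.54-fold (log2 change 1.82, SE 0.17, limma adjusted p = 0.00209). MIMAT0004674 fell from 43.6 ± 2.12 to 17.2 ± 1.80 (SD, n = 3 each; log2 change -1.34, SE 0.14, limma adjusted p = 0.00220), and MIMAT0004778 from 72.2 ± 8.78 to 29.5 ± 2.44 (SD, n = 3 each; log2 change -1.29, SE 0.15, limma adjusted p = 0.00317). The arrays do not separate cancer cells from other cells of a tumour, so which cells hold these changes was not measured. MIMAT0004674 ended below the array median, so its fall may be larger than the fold states.

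Tumour changes were also counted by level, without a test between levels. Of 219 probes from 50 to under 500 units, 13 rose and 31 fell, together 20.1%. Of 85 probes at 500 or more, 7 rose and 4 fell (12.9%), and of 878 probes under 50, 8 rose and 15 fell (2.62%). The spread between replicate tumours was smaller for brighter probes, with a median residual SD of 0.26 on the log2 scale under 50 units and 0.10 at 500 or more. All 78 changed probes had control and treated arrays that did not overlap; among all 1182 probes 346 (29.3%) did not overlap, where chance gives 10%. Between treated and control tumours the 75th percentile of the arrays was 51.1 against 53.8 (exact two-sided permutation p = 0.3). The number of probes at 100 units or more was 187 against 204 (exact two-sided permutation p = 0.1). With 3 arrays against 3 this permutation test allows no p under 0.1, so it could not have placed either difference beyond chance. The share of higher among changed probes was 35.9% as deposited, and 55.7% (34 higher, 27 lower) when the arrays were centred on their 75th percentile, which moved the median change of all probes to 0.11 on the log2 scale. With 5 arrays the count was lower whichever was left out: 28, 39 and 46 without control replicates 1, 2 and 3, and 50, 42 and 33 without metformin replicates 1, 2 and 3. It was 28 with all 24 arrays in 1 fit, and higher with 16 added before log2 (147), among the brighter 591 probes (149) and with a level-dependent robust prior variance (188).

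**Figure D3:**
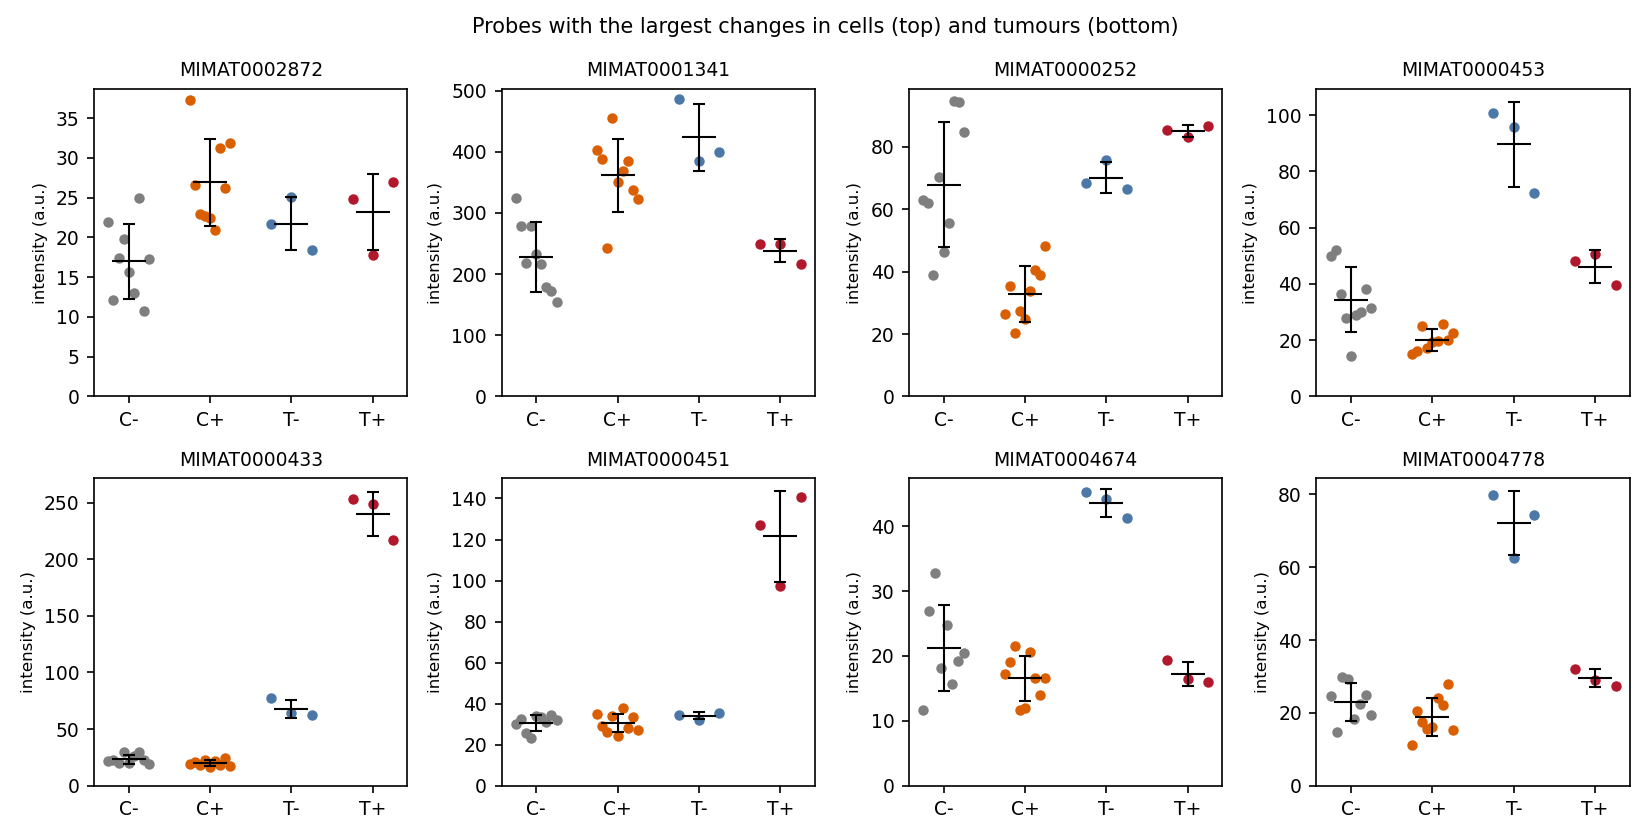
Intensity in arbitrary units on each array of 4 probes past the threshold, the largest rises and falls, in cells (top) and in tumours (bottom). C- and C+ are control and metformin cells, T- and T+ control and metformin tumours; bars give mean and SD. MIMAT0001341 is higher in C+ than C- and lower in T+ than T-.

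Whether metformin acted alike in cells and tumours was examined in 3 ways. The difference of the effects passed the threshold for 13 of 1182 probes, 6 with the more positive effect in tumours and 7 with the more negative. Centred on the 75th percentile, which moved the median difference of all probes to 0.15 on the log2 scale, 16 were more positive and 3 more negative. Of these 13, 12 were also called in tumours and 2 in cells, and 9 had effects of opposite sign. Choosing probes for a large difference of effects itself favours opposite signs. Such a sign can also rest on an effect near none, as for MIMAT0000451 with a log2 change of -0.0056 in cells (limma adjusted p = 0.986). Only MIMAT0001341 was called in both materials with opposite signs. The count of 13 was 8 without tumour control replicate 1, 8 without tumour metformin replicate 3 and 5 after quantile normalization, but 22 among the brighter probes, 34 with 16 added before log2 and 42 with array weights. MIMAT0000433 and MIMAT0000646 had the most positive differences. MIMAT0000433 was at 23.4 ± 4.04 in control cells and 19.8 ± 2.64 in metformin cells (SD, n = 9 each), and its effects differed by 2.06 on the log2 scale (SE 0.26, limma adjusted p = 1.18e-07). MIMAT0000646 rose from 62.1 ± 13.5 to 193 ± 6.77 in tumours (SD, n = 3 each), while its means in cells were 88.8 ± 35.1 and 69.5 ± 24.2 (SD, n = 9 each); its effects differed by 2.01 (SE 0.38, limma adjusted p = 0.000598), and after quantile normalization this difference did not pass (1.58, limma adjusted p = 0.547, the highest over all alternatives, of which the lowest was 4.27e-05). MIMAT0001341 rose in cells but fell in tumours, from 423 ± 54.7 to 238 ± 18.7 (SD, n = 3 each), and its effects differed by -1.51 (SE 0.28, limma adjusted p = 0.000546). MIMAT0005898, a bright probe of the tumours, fell there from 3413 ± 266 to 1533 ± 45.5 (SD, n = 3 each), with means of 110 ± 23.1 and 124 ± 35.0 in cells (SD, n = 9 each), a difference of effects of -1.29 (SE 0.30, limma adjusted p = 0.0110). Its limma adjusted p ranged over the alternatives from 0.000396 to 0.0508, the latter without tumour control replicate 1.

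Few probes were called in both materials. Of 12 that rose in cells and 28 that rose in tumours 0 were shared (0.284 expected from independent lists), and of 11 and 50 that fell 2 were shared (0.465 expected; one-sided Fisher's exact p = 0.0756 over probes). MIMAT0000453 was among them: in tumours it fell from 89.6 ± 15.2 to 46.1 ± 5.79 (SD, n = 3 each; log2 change -0.95, SE 0.18, limma adjusted p = 0.0177). MIMAT0001341 was the 1 probe that rose in cells and fell in tumours (0.508 expected), and 0 fell in cells and rose in tumours (0.261 expected). Over all 1182 probes the log2 changes of the materials correlated weakly, with Pearson's r = 0.261 and Spearman's rho = 0.279 across probes, which are not independent replicates. The jackknife SE of r over the 6 tumour arrays was 0.0582. For the 144 probes with a mean level of at least 100, r was 0.162, and for the 1038 dimmer probes 0.278. The changes had the same sign in 59.8% of probes, in 16 of the 23 called in cells and in 53 of the 78 called in tumours.

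**Figure D4:**
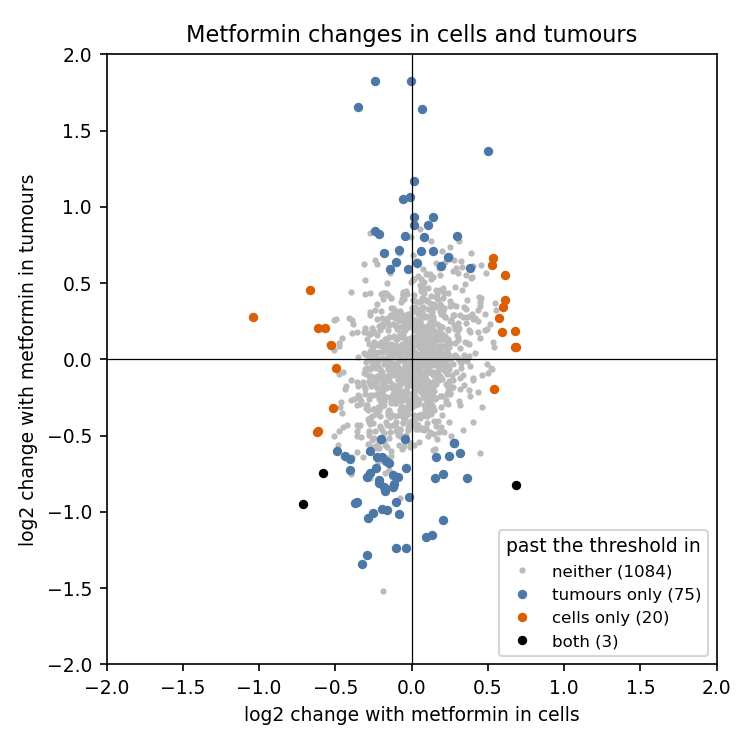
Log2 change with metformin in tumours against that in cells for 1182 probes. Colours mark probes past the threshold in tumours only, in cells only, in both or in neither; the 3 called in both include MIMAT0001341, which lies in the lower right with opposite signs.

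Untreated tumours were also set against untreated cells, as a description only, since material and array batch may be confounded. The tumours grew in mice and may hold cells of the host, which the arrays do not separate from the cancer cells. A probe that differs between the materials therefore need not have changed in the Panc1 cells. Of 1202 probes 593 passed the threshold, 371 higher in tumours and the others lower. The probe that joins MIMAT0000232 and MIMAT0004563 was at 20.0 ± 4.69 in control cells (SD, n = 9), below the array median, and at 1514 ± 77.3 in control tumours (SD, n = 3), 77.7-fold higher (log2 change 6.28, SE 0.21, limma adjusted p = 1.46e-25). MIMAT0001631 was at 20.2 ± 4.89 in cells (SD, n = 9) and 930 ± 91.4 in tumours (SD, n = 3), 47.1-fold higher (log2 change 5.56, SE 0.21, limma adjusted p = 4.64e-24). Both probes may lie at background in cells, which would make these folds too small. Their log2 changes depended on the scaling, from 4.94 and 4.14 after quantile normalization to 6.51 and 5.79 centred on the 25th percentile. The largest falls were in dim probes: MIMAT0000716 had 23.8 ± 3.40 in cells (SD, n = 9) and 11.2 ± 5.46 in tumours (SD, n = 3; log2 change -1.20, SE 0.22, limma adjusted p = 1.80e-05), and MIMAT0004549 had 22.6 ± 4.85 and 10.9 ± 5.22 (SD, n = 9 and 3; log2 change -1.17, SE 0.24, limma adjusted p = 9.85e-05). The log2 change of MIMAT0000716 was -2.03 centred on the 75th percentile, where that of MIMAT0004549 was larger as well, and with 16 added before log2 they were -0.57 and -0.53. The change of MIMAT0004549 was -0.71 without tumour control replicate 1. After quantile normalization it did not pass (limma adjusted p = 0.0714, the highest over its alternatives, of which the lowest was 3.15e-07).

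Dim and bright probes were again counted apart, by a level that includes the tumours, so a rise there itself moves a probe to a brighter class. Of 154 probes from 50 to under 500 units 134 were higher and 1 lower in tumours, and of 49 at 500 or more 38 were higher and 0 lower. Of 999 probes under 50, 199 were higher and 221 lower. The summed intensity was 1.96 times higher in tumours (exact two-sided permutation p = 0.00455, the smallest that 3 arrays against 9 allow; adjusted 0.0136 over 9 array-level tests), and the 25th percentile was 15.4 ± 1.03 in tumours (SD, n = 3) against 19.2 ± 0.475 in cells (SD, n = 9). With arrays deposited near a common level, the sum cannot show whether the total miRNA signal differed here either. Scaling set the split between directions: as deposited 62.6% of calls were higher, after quantile normalization 96 of 191 and after centring on the 75th percentile 159 of 957, which moved the median change of all probes to -0.85. After centring on the 25th percentile 455 of 518 were higher, with the median change at 0.21.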

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

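Of the tests in this part, the comparison of bright with dim probes, the centring on the 25th percentile and the splits of the cell arrays against the tumour effect were chosen after the data had been seen. Samples that stand apart in their group were sought in 32 sets of 9 arrays, and 3 were found, where chance gives about 5%. Control cell replicate 5 had 89 blanks, against 9 to 37 on the other control cell arrays. Control cell replicate 1 had a 75th percentile of 36.5, against 32.2 to 33.9. MIMAT0000453 had a log2 intensity of 3.83 in control cell replicate 5, against 4.80 to 5.71 on the others, and without that array its log2 change in cells was -0.86.

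The metformin effect differed between tumours and cells for 13 probes, by the interaction contrast. Among the probes given by number these were MIMAT0000433 (2.06 on the log2 scale, tumours minus cells), MIMAT0000646 (2.01), MIMAT0000451 (1.83), MIMAT0000252 (1.32), MIMAT0005898 (-1.29) and MIMAT0001341 (-1.51). Of 100 splits of the treatment labels within each material, 5 gave at least 13 probes, the real one included, and the highest other gave 36. All 5 were among the 8 splits that kept the real grouping of the tumours and with it the tumour effect, so their share does not measure chance. The 92 splits with other tumour groupings gave at most 1 probe. For the 23 probes called in cells, 1 of 100 splits was as large, the real one, a share under 0.05, and the highest other count was 13. These splits shuffled the cell arrays freely. Each number holds 1 control and 1 metformin array, and deviations of same-number cell arrays correlated over 0.1 in 8 of 9 pairs. Free splits break up these pairs, unlike the real grouping. They are thus not a matched reference and alone do not exclude chance.

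The first pattern is the 78 probes that changed in tumours. The 10 splits of the 6 arrays are too few for a share under 0.05; the real split gave 78 and the highest other 0 (1 of 10 as large). The tables argue against the single scaling factor per array as the whole source, since quantile normalization and 3 other centrings gave at least 61 calls, and against a uniform change in the share of tissue other than the cultured cells. Of the 75 probes at least 4-fold higher in untreated tumours than in cells, 16 fell and 7 rose with metformin, by medians of -0.81 and 0.81 on the log2 scale, against 34 and 21 of the 1107 others (more often called, two-sided Fisher's exact p = 2.38e-11 over probes, not matched for level, in comparisons that share the control tumours). The median over all 75 was -0.23 (quartiles -0.52 and 0.03), and choosing probes for being high in the same control tumours can itself favour falls. A smaller share of tissue other than the cultured cells may account for part of the falls and not for the 7 rises. A change in the makeup of that tissue, the 2 doses and a response of the cancer cells stay open, since no marker list could be matched.

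The second pattern is the 221 dim probes, under a mean level of 50, that were lower in untreated tumours than in cells. Whether they come from the authors' scaling, with arrays near a common median although tumours hold more bright probes, stays open. After centring on the 25th percentile 63 lower calls were left, but that centring lifts every probe in tumours, so the drop decides nothing. A common shift does not account for every difference, since 199 dim probes were higher as deposited, and after the centring 33.7% of the 999 were still past the threshold, 274 higher and 63 lower. For the whole comparison 1 of 100 splits was as large, the real one with 593, and the highest other count was 2. The other splits mix tumours with cells and put the difference of the materials into the residual spread, which itself keeps their counts low. They cannot tell material from array batch, which may be confounded. A difference in background or labelling, and lower levels of these miRNAs in tumours, were not tested.

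The third pattern is the correlation of the metformin effects between cells and tumours, 0.261. Of 100 splits of the cell arrays 1 was as large, the real one, a share under 0.05, but the highest other value was 0.225. The 10 splits of the tumour arrays, the reference fixed beforehand, are too few for a share under 0.05 (1 as large, highest other 0.244). Regrouped arrays thus came near the real value, and chance was not excluded. A background axis along which replicate cell arrays also differ was examined through the first component of their deviations only. Removing it left r at 0.277 over 772 dim probes, from 0.255 before, so that component is argued against as the source. It held 18.1% of these deviations, with absolute correlations of 0.0845 with the cell effect and 0.188 with the tumour effect. Other components were not removed, so a background source stays open. Whether bright probes share the response stays open, with r at 0.162 over probes of at least 100 units (95% interval -0.00127 to 0.317) and 0.278 over dimmer ones (0.221 to 0.333). These intervals, by Fisher's z, count probes as independent replicates and leave out the spread between arrays. They may therefore be too narrow. A response common to cells and tumours is thus a hypothesis only.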

How the results depend on the processing

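Centring on the 25th percentile and the mean level of at least 100 were chosen after the data had been seen; the cause of a changed count was not tested unless fewer probes or arrays explain it. In cells the count of 23 was 5 at a mean level of at least 100 (fewer probes tested), 14 at 1.5-fold or more and 13 with the unmoderated test, and between 12 and 32 with 1 array left out. In tumours the count of 78 was 147 with 16 added before log2 (46 higher, 101 lower), 149 in the upper part by level (42 and 107), 188 with a trended robust prior (60 and 128) and 28 with all 24 arrays in 1 fit (13 and 15), and between 28 and 50 with 1 array left out. Between untreated materials the count of 593 was 191 after quantile normalization (96 higher, 95 lower), 957 centred on the 75th percentile (159 and 798), 395 in the upper part by level and 97 at a mean level of at least 100, and between 416 and 625 with 1 array left out. For the difference of effects the count of 13 was 5 after quantile normalization (3 and 2), 34 with 16 added, 22 in the upper part by level, 42 with array weights and 3 at a mean level of at least 100, and between 8 and 18 with 1 array left out; centring on the 75th percentile gave 19 (16 and 3) and on the median 11 (7 and 4). The correlation of effects was 0.182 over the 100 probes with a mean level of at least 100 in each material (0.162 over the 144 whose average over both materials reaches 100) and between 0.213 and 0.290 with 1 tumour array left out. With the replicate number as a block (replicate block) cells gave 50 calls (28 higher, 22 lower; 21 shared with the 23) and tumours 40. Equal numbers were not taken to pair arrays. Deviations from the group means correlated over 0.1 in 8 of 9 cell pairs (0.0447 to 0.421) and 2 of 3 tumour pairs (0.0598 to 0.123). Between arrays of different number the median correlation was -0.00932 in cells and -0.0370 in tumours. Of the cell arrays 13 of 18 correlated best with their own number among 9 candidates, and of the tumour arrays 6 of 6 among 3. In cells a factor shared by number is therefore likely, though only the data hint at it. The main fits hold no block and leave such a factor in the residual spread. Of 201 values for probes given by number under alternatives with all arrays, 196 kept direction and side of the threshold, 5 lost the threshold and 0 reversed. Probes that a filter by level removed gave no value and were not counted. All these probes changed by more than 1.5-fold, so the 1.5-fold minimum could change none of them. With 1 array left out 239 of 240 values kept direction and side of the threshold and 1 lost the threshold. The looser filter on blanks left the same probes to test in the cell and tumour comparisons, so it could change nothing there. Tests of miRNA lists, with their alternatives, were not run, since the numbers were not paired with names. Signal over background could not be computed, which limits what dim probes show.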

Other observations

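The test of consecutive numbers in tumours and the division of calls by accession number were chosen after their results had been seen. Accession numbers of mature miRNAs are given out roughly in order of registration, and level followed them: of the 588 tumour-tested probes below the median number 24.7% had a mean level of at least 100 in tumours, against 9.01% of the 588 above it (two-sided Fisher's exact p = 5.89e-13 over probes). The direction of the metformin change in tumours was divided as well. Below the median number 25 probes rose and 29 fell, and above it 2 rose and 21 fell (two-sided Fisher's exact p = 0.00152 over probes, which are not independent replicates). With the arrays centred on the 75th percentile the counts were 30 and 17 below, 3 and 10 above. Among called probes of at least 100 units they were 14 and 14, and 0 and 8.

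Consecutive accession numbers may belong to related miRNAs, such as the arms of 1 hairpin or members of 1 cluster, so their changes were set against each other. Over 1056 consecutive pairs in cells the log2 changes correlated with r = 0.109, and over 1004 pairs in tumours with r = 0.0752. In a one-sided permutation test, with changes permuted 10000 times among probes of similar mean level, p was 9e-04 in cells and 0.0213 in tumours, with highest permuted values of 0.123 and 0.134. In tumours 7 consecutive pairs were called in the same direction and 3 in opposite directions; in cells 0 pairs were both called. The correlation is consistent with a small part of the changes being shared by related probes, and joint expression was not separated from cross-hybridization of similar sequences.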
